A study of Mus musculus with 8 samples.

How the data were processed

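The libraries were made from dissociated cortex cells of APOBEC1-YTH mice after tamoxifen, per the labels, by split-pool barcoding of fixed whole cells and polyA RNA (Parse Biosciences kit). The series' design text instead describes sorted, NeuN-stained nuclei and total RNA. The accounts differ, and the sample protocols were followed here. All 8 libraries carry the group aged, as 4 lanes of each of 2 sublibraries. The young cells belong to a companion series and enter only through the authors' deposited table.

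The submitters' processing notes name the genome build mm10 and STAR 2.7.5, and the series' design text names the Bullseye pipeline for finding C-to-U sites. Read filters, handling of molecular identifiers, normalisation of the ages for depth and the test behind the p-values are not given in the sources used here. Whether the young libraries were made with the same kit is not given either. Of the deposited data, the table of differentially methylated sites was analysed. Per-cell expression and cell types were not analysed here.

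The units below were read from the file headers and tested on the values. The authors' table gives the percent of cells methylated at each site, and at all 2055 sites these percentages give the same 2623 young cells and, at the 2036 sites with a methylated aged cell, the same 846 aged cells. Cells without reads at a site therefore count as unmethylated. The deposited counts are numbers of methylated cells, not reads. The deposited C-to-U fraction is a mean over all cells of an age, printed here as a percent, and the fraction within methylated cells was computed from it by dividing by their share. The authors' log2 fold is the log2 of the young over the aged mean fraction, and its sign was turned so that positive values mean higher in aged cells. The deposited p-value and adjusted p-value of each site are the authors' own. All listed adjusted p-values were under 0.05. Their ratios to the p-values are those of a Benjamini-Hochberg adjustment over 29127 sites, with whole implied ranks (within 0.001) at 90.6% of listed sites and rank 5870 for the largest listed p. The table lists 2055 of the sites down to that rank, so it was filtered further: no listed site has fewer than 25 methylated cells over both ages or an absolute log2 ratio under 0.58. Since cells of 1 animal are not replicates, no test of a single site was added.

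Sites were placed on GENCODE M21 transcripts (GRCm38) by gene name (780 genes), by an older name (6) or not at all (3). The deposited position was read as counted from 0, and positions printed here count from 1. Read in this way the edited base was C on the gene's strand at 1982 of 2049 sites and G at the 67 sites of CT010467.1, while the other reading gave C at 209. Each site took its region from the highest-ranked transcript of its gene with an exon at that site. The class of noncoding exons therefore also holds sites in noncoding transcripts of coding genes, as at Atp2b1 and Ptprd. Conversely, Snhg11, a member of the long noncoding RNA list, is annotated as protein coding. Of its 51 sites, 46 therefore counted as 3' UTR and 3 as coding sequence. The 41 bases around a site occurred in another annotated gene for 45 sites. Unannotated copies were not searched.

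Direction was the sign of aged minus young mean C-to-U, with the share of methylated cells and the fraction within them beside it. Shares carry Clopper-Pearson 95% intervals, and a count of 0 carries a floor of 3 counts. Regions and gene groups were compared by two-sided Fisher exact tests across sites or genes of the table, with Benjamini-Hochberg adjustment over the 11 groups of at least 5 genes. Agreement within genes was compared with 10000 reassignments of directions. Intervals in the closing section come from 1000 resamplings of genes. The tests were tried on simulated tables of the same size. They recovered 88% of simulated groups of 25 genes with 80% higher and called 3.14% of groups with no shift. The simulated genes had the 41.5% of sites as their base rate, while 55.8% of the real genes were higher. A shift to 80% was therefore larger in the simulation than it would be among the real genes. Most groups tested also held fewer than 25 genes. The 88% thus overstates the recovery for real groups, and a group that did not pass may still differ. The test of shared direction fell under 0.05 in 8% of tables with none simulated.

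Before the data were examined, 21 gene lists, the tests and most alternatives were fixed. The pattern behind the ion channel list also took in the noncoding RNA Kcnq1ot1, which was kept as fixed and left out in an added alternative. The named genes were the 12 with the largest increase and the 12 with the largest decrease in mean C-to-U, up to 4 per list by absolute difference, and the 5 genes with the most sites. Genes named outside this rule, namely Calm2, Ppp3ca, Kcnq1ot1 and some in the closing section, were chosen after their values were seen. A few genes that the rule names are not reported here. The fixed alternatives were an adjusted p under 0.01, a minimum difference of 10 points, the gene as unit, gene means, other windows of 500 bases and site spacings of 10 bases. Alternatives chosen after seeing the data were direction by share or by in-cell fraction, a minimum log2 fold of 1, at least 10 methylated cells per age, leaving out CT010467.1 and copied sites, only C after A, another transcript choice and region as a stratum. Comparison with random gene sets matched on region (2000 per fixed list) was also added then. A coverage minimum, leaving out single libraries and comparisons between cell types were not run, since the table has no coverage, library or cell type values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.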

Results

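The measurements came from cortex cells of mice carrying APOBEC1-YTH, a cytidine deaminase fused to the YTH domain that binds N6-methyladenosine (m6A). The fusion converts C next to a methylated A to U, so that C-to-U changes in sequencing reads mark m6A in single cells (the scDART-seq assay). All 8 libraries belonged to 1 group, aged mice of 12 to 14 months at the start of treatment. They were 4 lanes of each of 2 sublibraries and not biological replicates, and the number of mice was not given in the sources used here. The mice received tamoxifen at 20 mg/kg every 24 h for 5 days, and cortex was collected 7 days after the last dose. The values came from the authors' deposited table of sites that differed between aged and young cells. That table lists 2055 sites in 789 genes, measured over 846 aged and 2623 young cells. It holds no site with an absolute log2 ratio of mean C-to-U under 0.58, so smaller differences were outside the comparison.

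The table gives no value per library or per mouse, so no value below has a replicate error. It gives no reads per site either, so the read depth could not be measured. The number of cells sets the precision. A share of methylated cells is given with its exact binomial (Clopper-Pearson) 95% interval, which covers counting error only. The median site had 30 methylated young cells and 21 methylated aged cells, and no site had fewer than 25 over both ages. A count of 0 among the 846 aged cells allows a share of up to 0.355%, taking 3 counts as the limit in place of the two-sided interval.

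The main comparison asked at which sites m6A-marked RNA differed between aged and young cortex cells. Mean C-to-U over all cells was higher in aged cells at 852 sites and lower at 1203. Luc7l3, a splicing factor, had the largest increase, and App, the amyloid precursor protein gene, had the largest decrease. The microtubule genes Kif1a and Map1b, the active zone scaffold Pclo and the dystrophin gene Dmd stood with Luc7l3 among the 12 genes with the largest increases, each ranked by its site with the largest difference. The AMPA receptor genes Gria2 and Gria3, the NMDA receptor gene Grin2b and the GABA-B receptor gene Gabbr1 stood with App among the 12 genes with the largest decreases. Of the 12 largest increases, 9 lay in coding sequence and 0 in a 3' UTR, while 9 of the 12 largest decreases lay in a 3' UTR and 0 in coding sequence.

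The Luc7l3 site was in exon 8 of 11, in coding sequence, on chromosome 11 at position 94297059 (mm10). Its mean C-to-U was 1.07% in young and 14.5% in aged cells, a log2 ratio of 3.76, with an adjusted p of 3.19e-136 in the authors' deposited table. Methylated cells made up 8.92% (7.86 to 10.1) of young and 37.5% (34.2 to 40.8) of aged cells. Kif1a, a kinesin that carries synaptic vesicle precursors, went from 1.56% to 12.3% at position 93055713 on chromosome 1, with methylated cells at 3.43% (2.77 to 4.20) and 19.1% (16.5 to 22.0). Ptprd, a receptor tyrosine phosphatase of synapses, went from 1.14% to 11.1%. Dlgap4, a postsynaptic scaffold, went from 1.15% to 9.30%, and Pclo from 0.664% to 7.99%. Dmd had a mean of 0.421% in young and 7.35% in aged cells, a log2 ratio of 4.13. Map1b, a microtubule-associated protein, went from 1.14% to 7.98%. Zfp91, a zinc finger ubiquitin ligase, went from 1.67% to 8.88%, and Uggt2, a glycoprotein quality control enzyme of the endoplasmic reticulum, from 2.09% to 9.01%. Atp2b1, a plasma membrane calcium pump, went from 2.86% to 8.99%, and the cell adhesion gene Nptn from 0.851% to 6.93%. At each of these 11 sites both the share of methylated cells and the C-to-U fraction within them were higher in aged cells. Other sites of these genes did not all follow by mean: 4 of 10 sites were higher in Luc7l3, 5 of 15 in Kif1a, 4 of 10 in Map1b, 2 of 5 in Atp2b1, 11 of 17 in Pclo and 2 of 2 in Dmd, while by share 10, 14, 8, 5, 17 and 2 of them were higher. The remaining increase, at Gm37376 (22.2% to 34.9%), lay in an unclassified transcript antisense to Malat1. Its C did not follow an A, and whether the reads came from Gm37376 or from the opposite strand was not settled, so the assignment to this gene is in doubt.

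The App site was in the 3' UTR, in exon 16 of 16, on chromosome 16 at position 84955148. Its mean C-to-U was 12.3% in young and 1.85% in aged cells, a log2 ratio of -2.74, with an adjusted p of 6.37e-09 in the authors' deposited table. Methylated cells made up 38.1% (36.2 to 39.98) of young and 3.31% (2.21 to 4.75) of aged cells. All 12 listed App sites had a lower mean in aged cells, and 10 of the 12 also had a lower share of methylated cells. Gria3 went from 9.85% to 1.27% on the X chromosome at position 41676534, and its methylated cells were 22.2% (20.6 to 23.8) of young and 1.65% (0.908 to 2.76) of aged cells. Gria2 went from 7.28% to 1.76%, with methylated cells at 34.9% (33.1 to 36.8) and 4.14% (2.90 to 5.71). Vsnl1, a neuronal calcium sensor, went from 9.79% to 1.62%, and Gabbr1 from 9.26% to 2.83%. Ywhaz, a 14-3-3 adaptor protein gene, went from 5.27% to 0.0874%, a log2 ratio of -5.91, and Tulp4 from 6.28% to 1.13%. Gm47283, a predicted gene on the Y chromosome, went from 11.9% to 2.54% at an intronic site, and 4 of its 5 other sites have their surrounding bases in another annotated gene, so the assignment to this gene is in doubt. Tmem59l had a mean of 6.18% in young cells, with 202 methylated cells, and was methylated in 0 of 846 aged cells, which allows a share of up to 0.355%. Grin2b went from 9.71% to 3.71%, but the mean over its 11 listed sites was 0.0287 points higher in aged cells. The C-to-U fraction within methylated cells was higher in aged cells at 10 of the 12 largest decreases. At App it was 32.4% in young and 55.9% in aged cells. In the authors' deposited table the adjusted p was 1.03e-32 at Gria2, 5.69e-07 at Tmem59l, 5.14e-05 at Tulp4 and 0.000143 at Ywhaz. It was 0.00151 at Gria3, 0.0019 at Gabbr1, 0.0237 at Grin2b, 0.0297 at Vsnl1 and 0.043 at Gm47283. The authors' test is not given, so why some values lay near the threshold although the intervals of the shares lay far apart is not settled.

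**Figure D1:**
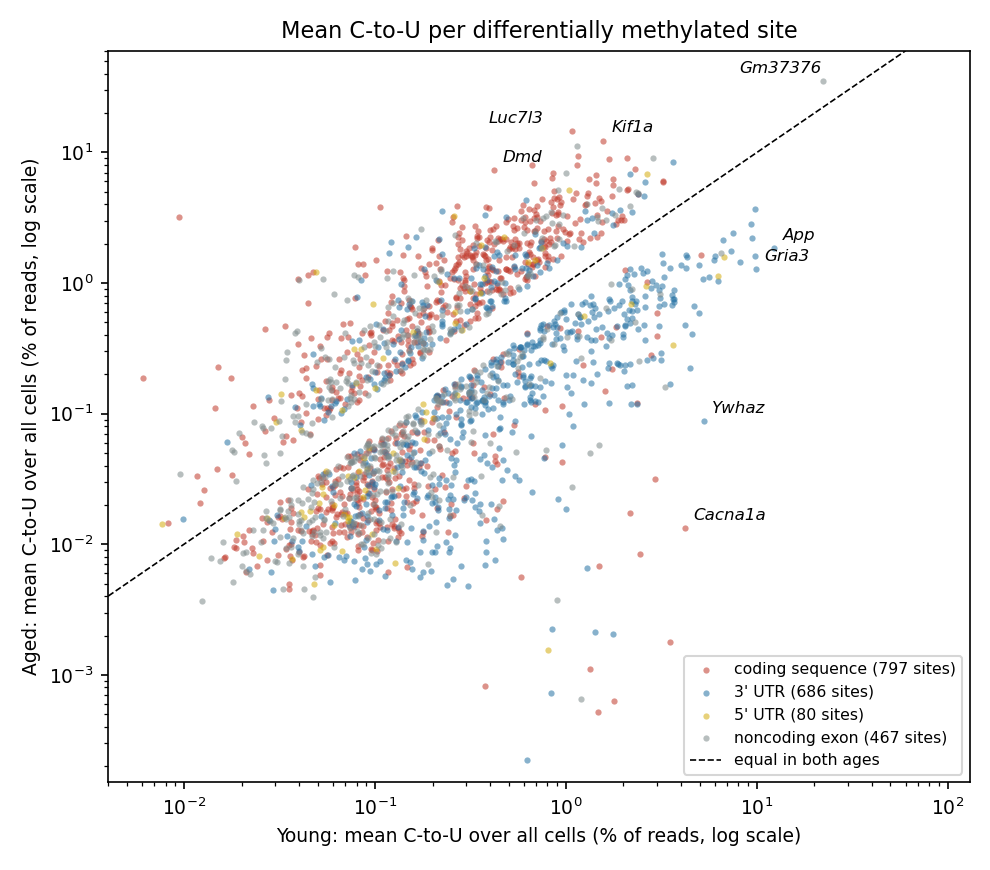
Mean C-to-U over all aged cells (y, percent, log scale) against that over all young cells (x, percent, log scale), with 1 point per listed site coloured by transcript region. Luc7l3, Kif1a and Dmd lie far above the dashed line of equality and App, Gria3 and Ywhaz far below it; the 19 sites with no methylated aged cell and the 6 sites outside annotated exons of their gene are not drawn.

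**Figure D2:**
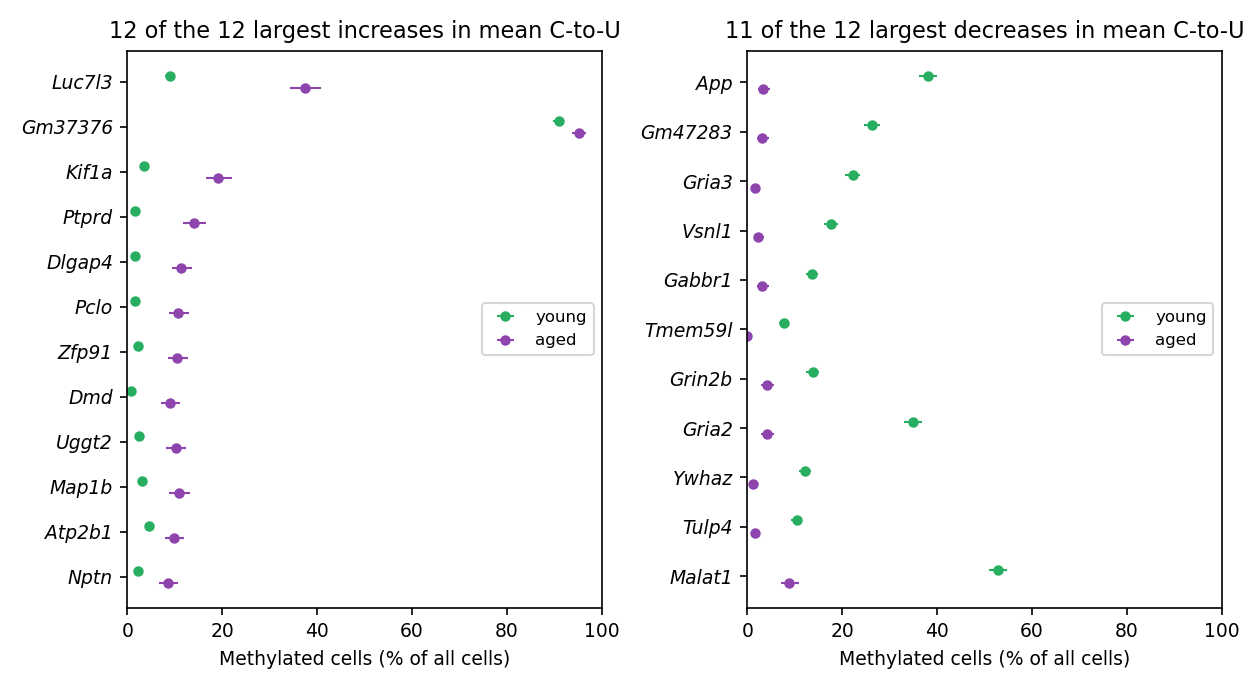
Share of methylated cells (x, percent of all cells of that age) at the 12 genes with the largest increase (left) and 11 of the 12 with the largest decrease (right) in mean C-to-U, for young and aged cells. Points are shares and bars their exact binomial 95% intervals; all 12 shares at left were higher and all 11 at right lower in aged cells.

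Among the 852 sites with a higher mean, the median log2 ratio was 1.55, a 2.93-fold difference, with an interquartile range of 1.05 to 2.22. Among the 1184 sites with a lower mean and at least 1 methylated aged cell, the median log2 ratio was -1.75, a 3.37-fold difference, with an interquartile range of -2.59 to -1.11. The median difference was 0.526 points at higher sites and -0.121 points at lower sites. The direction depended on the measure. By share of methylated cells, 1550 sites were higher and 505 lower in aged cells. By C-to-U within methylated cells, 650 were higher and 1386 lower. At 725 sites the mean was lower although the share of methylated cells was higher. The median share of methylated cells was 1.14% in young and 2.48% in aged cells, while the median C-to-U within methylated cells was 18.0% in young and 7.22% in aged cells. Cells without reads at a site count as unmethylated in these shares and means, so a difference in expression or coverage between the ages enters them.

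The next comparison asked whether the sites of a gene moved together. Snhg14, the noncoding host transcript of an imprinted snoRNA cluster, had 16 of 16 sites higher in aged cells by mean and by share. Ppp3ca, a calcineurin catalytic subunit gene, had 0 of 16 higher by mean. Rbm25, a splicing regulator, had 17 of 26 sites higher by mean and 26 of 26 by share. Gria2 had 4 of 25 sites higher by mean, Snap25, a vesicle fusion gene, 2 of 27, and Camk2n1, an inhibitor of CaM kinase II, 1 of 13. These genes were picked for their site counts after the values were seen. Of the 311 genes with 2 or more sites, 143 (46.0%) had all sites in the same direction of the mean, and 168 had sites in both directions. Random reassignment of directions over sites gave 32.8% (95% range 28.3 to 37.3), with a permutation p of 0.0001, the smallest that 10000 reassignments can give. This test is across sites in the table, not across mice. The reassignment did not keep the transcript region of the sites, and direction differed between regions, as described below. Sites of a gene can also share a region or lie on the same reads. The test therefore cannot tell sites of a gene moving together from an effect of region or of shared reads.

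The 5 genes with the most sites held 376 of the 2055 sites (18.3%). Meg3, an imprinted noncoding RNA of neurons, had 60 of 144 sites higher by mean but 143 of 144 higher by share of methylated cells. Its site with the largest difference went from 1.29% to 4.04%, with methylated cells at 6.10% (5.21 to 7.08) of young and 17.3% (14.8 to 20.0) of aged cells. Malat1, a nuclear noncoding RNA, had 29 of 87 sites higher by mean and 75 higher by share. Its largest difference was a decrease from 6.52% to 1.70%, with methylated cells at 52.8% (50.9 to 54.8) and 8.87% (7.04 to 10.99). CT010467.1, annotated as ribosomal RNA, had 11 of 67 sites higher by mean and 2 of 67 by share. At those 67 sites the edited C lay on the strand opposite to the annotated gene, so the assignment to this gene is in doubt. Snhg11 had 20 of 51 sites higher by mean and 41 by share. Its site with the largest difference fell from 3.18% to 0.948%, although the mean over its sites was 0.00978 points higher in aged cells. At Snap25 the largest difference was a decrease from 4.27% to 1.30% in the 3' UTR.

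A further comparison asked whether the direction differed between transcript regions. Sites in 3' UTRs were mostly lower in aged cells and sites in coding sequence were mostly higher. In 3' UTRs 168 sites were higher and 529 (75.9%) lower, as at App, Gria2, Gria3 and Vsnl1. In coding sequence 465 sites (57.8%) were higher and 339 lower, as at Luc7l3, Kif1a, Pclo and Map1b. In noncoding exons 187 of 468 sites were higher, and in 5' UTRs 29 of 80. The odds of being higher were 0.314 times those of other regions for 3' UTR sites (two-sided Fisher exact p = 4.14e-31, across sites in the table). By share of methylated cells, 761 of 804 coding sites (94.7%) and 343 of 697 sites in 3' UTRs (49.2%) were higher, with an odds ratio of 0.121. By C-to-U within methylated cells the odds ratio of 3' UTR sites against all other regions was 1.39, in the opposite direction (Fisher exact p = 0.000891). By this measure 3' UTR and coding sites were close, with 252 of 686 and 284 of 797 higher. Noncoding exons (98 of 467) and 5' UTRs (12 of 80) had a lower proportion of higher sites. Within genes that had both kinds of site, coding sites had the larger log2 ratio of shares in 58 of 73.

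**Figure D3:**
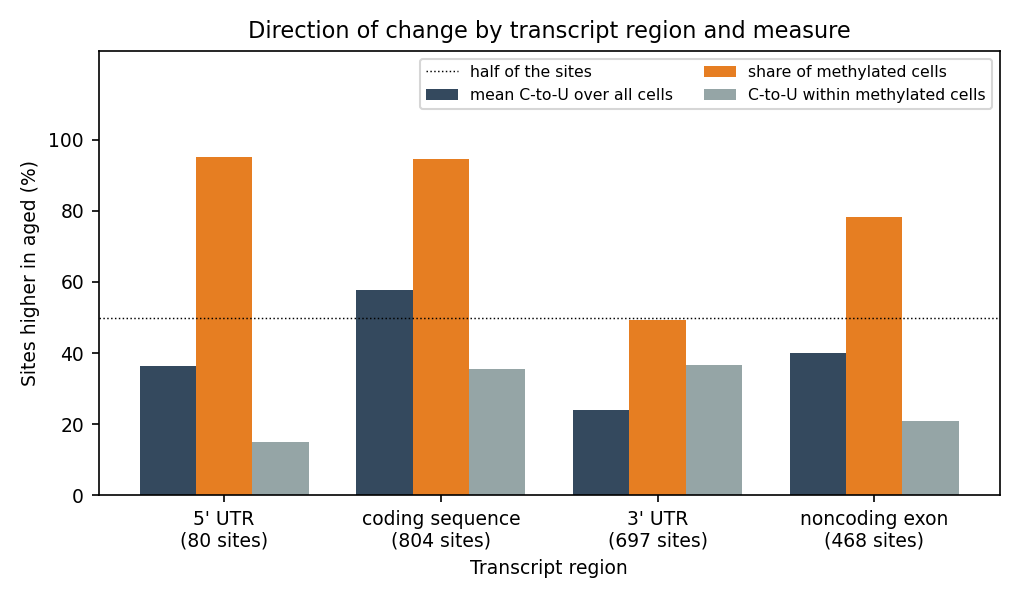
Percent of listed sites higher in aged cells (y) by transcript region (x, with the number of sites), for 3 measures: mean C-to-U over all cells, share of methylated cells, and C-to-U within methylated cells. By share, 94.7% of coding sites and 49.2% of 3' UTR sites were higher; the dotted line marks equal numbers of higher and lower sites.

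The sequence comparison described the sequence around the sites, since the edited C follows the methylated A in this assay. The edited C followed an A at 76.3% (74.4 to 78.1) of 2044 sites, against 25.7% (25.3 to 26.02) of the other C within 100 bases. The A lay in RAC (R being A or G) at 71.4% (69.4 to 73.3) of sites against 14.2%, and in DRAC (D being A, G or T) at 64.1% (62.0 to 66.2) against 11.9%. The App site with the largest decrease had ATACA around its edited C and so lay outside both motifs. Sites higher in aged cells had C after A at 84.6% (81.9 to 86.9) and sites lower at 70.4% (67.7 to 73.0). Coding and 3' UTR sites were close, at 80.1% (77.2 to 82.8) and 80.7% (77.6 to 83.6). The abundant noncoding RNAs were lower, with 61.5% (53.0 to 69.5) in Meg3, 43.7% (33.1 to 54.7) in Malat1 and 59.7% (47.0 to 71.5) in CT010467.1. The Luc7l3, Kif1a, Dlgap4, Zfp91 and Atp2b1 sites had the sequence GAACG around the edited C, as had the Malat1 site with the largest decrease. RAC and DRAC leave out the base after the edited C. The G at that base was therefore not compared with other sites, and GAACG is not added evidence of m6A.

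The last comparison asked whether gene groups fixed before the data were examined went in 1 direction, each gene taking the direction of its site with the largest difference. By that rule 440 genes were higher and 349 lower in aged cells. A gene's largest site did not always stand for its others: of the 187 genes with 2 or more sites that were higher by this rule, 40 had more sites lower than higher, and of the 124 that were lower, 1 (Gria3) had more sites higher. Calcium signalling was the group that passed the test, with 2 of 18 genes higher and 16 lower (odds ratio 0.115, Fisher exact adjusted p = 0.00131 over 11 groups). Atp2b1 and the calmodulin gene Calm2 were the 2 higher genes, although 2 of 5 Atp2b1 sites and 2 of 8 Calm2 sites were higher and the others lower. Among the lower genes, Vsnl1 is described above. Camk2n1 went from 6.01% to 1.61%, with methylated cells at 35.8% (33.9 to 37.6) of young and 5.08% (3.70 to 6.79) of aged cells. The plasma membrane calcium pump gene Atp2b2 went from 5.60% to 1.11%. For 15 of the 18 genes the site with the largest difference lay in a 3' UTR. With region as a stratum the odds ratio was again 0.115, and the adjusted p of 0.163 (0.0148 before adjustment) did not pass the threshold. Against 2000 random gene sets matched on region, a comparison also chosen after seeing the data, its 11.1% of genes higher stood below a median of 38.9% (95% range 16.7 to 61.1), and 99.9% of the sets had a percentage as high or higher.

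No other group passed this test as fixed. Of the ion channel and transporter genes, 6 of 21 were higher (Fisher exact, adjusted p = 0.0745). Kcnq1ot1, a noncoding RNA that the list took in by its name, was 1 of the 6. Without it, a setting chosen after seeing the data, 5 of 20 were higher (odds ratio 0.273, Fisher exact, adjusted p = 0.0321), which passes the threshold, while with region as a stratum and the list as fixed the adjusted p was 0.333. Cacna1e, an R-type calcium channel, went from 2.29% to 7.44%. Cacna1a, the P/Q-type calcium channel, went from 4.17% to 0.0133%, with 139 methylated young and 13 methylated aged cells. Within those cells its C-to-U was 78.8% in young and 0.862% in aged cells. The drop thus came mostly from the fraction in a few aged cells whose read depth is not given. Scn2a, a voltage-gated sodium channel, went from 2.99% to 0.392%. Of the postsynaptic genes 10 of 22 were higher (Fisher exact, adjusted p = 0.606). Dlgap4 stood among the higher and Gria2, Gria3 and Grin2b among the lower ones, although 4 of the 6 Gria3 sites and 5 of the 11 Grin2b sites were higher by mean. With sites in place of genes this group was lower, at an odds ratio of 0.504 and an adjusted p of 0.00246. By direction of the share of methylated cells its odds ratio was 0.227, with an adjusted p of 0.00372. Of its sites 86 of 130 lay in 3' UTRs, as did the largest site of 15 of the 22 genes, and with genes as unit and region as a stratum the odds ratio was 1.03, in the opposite direction, with an adjusted p of 0.951. Of the presynaptic genes 17 of 25 were higher (Fisher exact, adjusted p = 0.417), among them Pclo, Cplx2, a complexin (2.15% to 6.85%), and the calcium sensor of vesicle release Syt1 (1.03% to 5.14%). By site this group ran the other way, with 45 sites higher and 80 lower (odds ratio 0.786, Fisher exact, adjusted p = 0.351), and 18 of the 24 Syt1 sites were lower. Of the cytoskeletal genes 18 of 24 were higher (Fisher exact, adjusted p = 0.189), among them Kif1a, Map1b, Map1a (0.702% to 3.87%) and the spectrin gene Sptbn1 (0.383% to 3.78%), while by site 31 were higher and 39 lower.

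Of the neurodegeneration-associated genes 3 of 11 were higher (Fisher exact, adjusted p = 0.189). App and Prnp, the prion protein gene (0.689% to 0.162%), were lower, and Itm2b (0.535% to 1.33%) and the kinase gene Ptk2b (0.397% to 0.856%) were higher. With sites in place of genes the odds ratio of this group was 0.2999, with an adjusted p of 0.0175. App alone held 12 of its 30 sites and 12 of its 25 lower ones, 19 of the 30 sites lay in 3' UTRs, and with genes as unit and region as a stratum the adjusted p was 0.433. By share of methylated cells 7 of the 11 genes (odds ratio 0.562) and 15 of the 30 sites were higher. Of the long noncoding RNAs 16 of 22 were higher (Fisher exact, adjusted p = 0.283), among them Snhg14 (1.004% to 6.93%), 2900079G21Rik (0.837% to 3.48%) and Meg3. By mean 145 sites of this group were higher and 194 lower, with 60 of 144 higher in Meg3, while by share 311 of its 339 sites were higher. Of the RNA binding and splicing genes 18 of 30 were higher (Fisher exact, adjusted p = 0.868). Examples were Rbm25 (1.49% to 4.51%), Hnrnpu, a nuclear RNA-binding protein gene (0.870% to 4.51%), the helicase gene Dhx15 (2.11% to 5.24%) and Celf2 (1.01% to 3.24%), at their largest sites. By site 45 were higher and 45 lower in this group, with 2 of 7 higher in Hnrnpu and 1 of 4 in Celf2. Of the chaperone, ubiquitin and proteasome genes 8 of 14 were higher (Fisher exact, adjusted p = 1). They included the chaperone genes Hsp90ab1 (3.21% to 6.04%) and Hspa8 (0.985% to 2.44%) and the deubiquitinase gene Usp34 (0.263% to 1.31%), while Hspa12a went from 2.08% to 0.161%. The Hspa8 site has copies of its surrounding bases in other annotated genes.

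Of the genes of the m6A machinery 3 of 5 were higher (Fisher exact, adjusted p = 1). These were Zc3h13, a writer complex subunit (0.136% to 0.706%), the nuclear reader Ythdc1 (0.394% to 1.03%) and the translation factor Eif3a (0.309% to 1.85%). Prrc2a, a reader, went from 0.0676% to 0.0176%, although its share of methylated cells was 0.419% (0.210 to 0.749) in young and 2.36% (1.45 to 3.63) in aged cells. Of the excitatory neuron markers 2 of 5 were higher (Fisher exact, adjusted p = 0.868), with Camk2a lower (2.04% to 0.236%) and Nrgn higher (0.408% to 1.32%) at its largest site, with 1 of its 4 sites higher. The glutamate transporter gene Slc17a7 went from 0.210% to 0.0190%, and the transcription factor gene Mef2c from 0.152% to 0.0448%. At both sites the share of methylated cells was higher in aged cells, from 1.07% to 1.89% and from 1.30% to 1.42%. By share 18 of the 25 sites of this group were higher. The edited C did not follow an A at the named sites of Slc17a7, Mef2c, Nrgn, Prrc2a, Usp34 and 2900079G21Rik, so these may not mark m6A.

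The groups with fewer than 5 genes in the table were not tested. Of the astrocyte markers 3 of 3 were higher in aged cells, among them Slc1a2, a glutamate transporter (0.617% to 4.32%), and Sparcl1 (0.335% to 0.663%). This count rests on the largest site of each gene: 6 of the group's sites were higher and 6 lower, and 6 of the 10 Slc1a2 sites were lower. Of the oligodendrocyte markers 2 of 2 were higher, among them the RNA-binding protein gene Qk (0.787% to 2.10%). Of the precursor markers, Tnr was higher (0.404% to 0.929%) and Cspg5 lower (0.0799% to 0.0329%). Of the activity-regulated genes, Homer1 was higher at its largest site (0.297% to 0.875%), with 1 of its 3 sites higher, and Egr3 was lower (1.18% to 0.548%). Uqcrc2, the only oxidative phosphorylation gene in the table, was lower (0.730% to 0.436%). The markers of microglia, of endothelial and mural cells and of inhibitory neurons had 0 genes in the table, as had the cytosolic ribosomal and the inflammation groups. The table does not assign sites to cell types, so these markers show only which transcripts were listed.

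**Figure D4:**
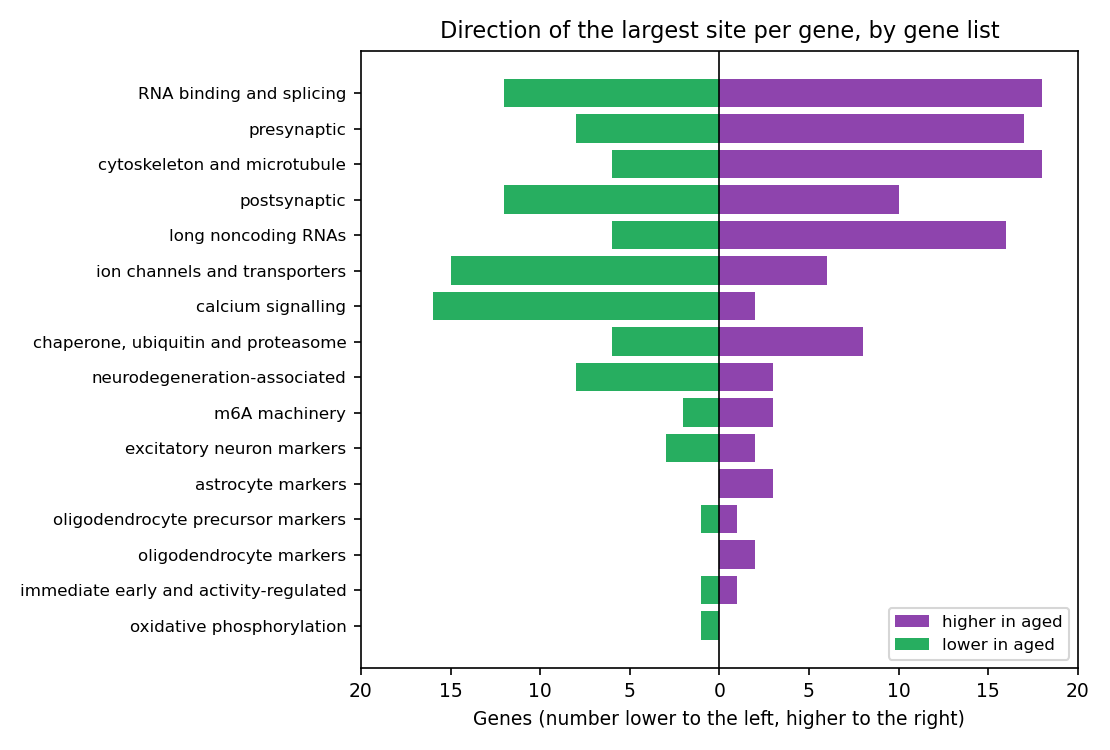
Number of genes (x) whose site with the largest difference was higher (right) or lower (left) in aged cells, for each gene group with at least 1 gene in the table (y). Calcium signalling had 2 genes higher and 16 lower.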

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

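The measure-based directions, the minimum log2 fold, the 10-cell minimum, the C-after-A restriction, the removal of copied sites, the other transcript choice and the region strata were chosen after seeing the data. With a minimum difference of 10 points, 3 sites were higher and 1 lower in aged cells. With the gene as unit 440 genes were higher and 349 lower, and by share of methylated cells 1550 and 505 sites. The majority direction thus turned in these 3 settings, though with the 10-point minimum too few sites were left to judge it. A gene took the sign of its largest difference, and the median difference was 0.526 points at higher and -0.121 points at lower sites. The gene rule can therefore lean towards higher, and how far was not tested. For the share the cause was not tested. Averaged per gene, the median log2 ratios were 1.46 and -1.55. The odds ratio of 3' UTR sites lay between 0.121 and 0.389 in 6 of its 7 alternatives and was 1.39 by C-to-U within methylated cells, in the opposite direction, and the cause was not tested. C followed A at 87.9% with 1 site per gene, and at 23.5% of other C within 500 bases. The calcium signalling group had adjusted p between 1.27e-09 and 0.163, the last with region as a stratum (odds ratio 0.115). Postsynaptic genes passed with sites as unit (0.504) and by share (0.227), and neurodegeneration-associated genes with sites as unit (0.2999); ion channel genes passed without Kcnq1ot1 (0.273), also chosen after seeing the data; the cause was not tested. Odds ratios of groups that passed in neither setting crossed 1 for presynaptic genes with adjusted p under 0.01 (0.999) and by site (0.786), excitatory markers by share (1.02) and the m6A machinery with adjusted p under 0.01 (0.856). With region as a stratum they did so for postsynaptic genes (1.03), the m6A machinery (0.476) and chaperone genes (0.918). The cause was not tested. The gene means of Grin2b (0.0287 points) and Snhg11 (0.00978 points) were reversed against their named sites. Of the 69 named sites, 8 had an adjusted p of 0.01 or more, among them those of Grin2b, Vsnl1 and Camk2a. A coverage minimum and an overlap between cell types were not run, because the table holds neither. Sites with under 25 methylated cells or an absolute log2 ratio under 0.58 are not in the table, so rarer or smaller changes were outside its reach.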

Other observations

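The tests of the region pattern by distance from the transcript end and by in-cell fraction were chosen after the result was seen. Sites with no methylated aged cell numbered 19, in 19 genes, and 11 of them lay in 3' UTRs. The genes were picked after their values were seen. Besides Tmem59l they included the neuronal membrane glycoprotein gene Gpm6a (204 methylated young cells), Ppp3ca (189), the axon guidance gene Dpysl2 (141) and Cnot7, a subunit of the CCR4-NOT deadenylase (109). A count of 0 among 846 aged cells allows a share of up to 0.355%, against 7.78% of young cells at Gpm6a, 7.21% at Ppp3ca, 5.38% at Dpysl2 and 4.16% at Cnot7. The edited C lay in coding sequence at Cnot7 and in the 3' UTR at the other genes named here. In the authors' deposited table the adjusted p was 0.0300 at Gpm6a, 0.00168 at Ppp3ca, 0.0240 at Dpysl2 and 2.96e-07 at Cnot7. Sites with no methylated young cell numbered 0. Listed sites have at least 25 methylated cells, and there were 2623 young but 846 aged cells. A site absent in young cells therefore needed a larger share of the other age to be listed, so these counts do not compare loss with gain.

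Some genes had coding and 3' UTR sites that moved apart by share of methylated cells. In App the median log2 ratio of shares, aged over young, was 1.12 at coding sites and -3.52 at 3' UTR sites. In Gria2 it was 1.47 and -2.60, in Snap25 1.22 and -2.72, in Camk2a 2.51 and -1.54, and in Gria3 2.36 and -3.75. The opposite order was present in Ttc3, with 1.31 at coding and 2.80 at 3' UTR sites, and in Zfp91, with 2.18 and 3.22. These genes were picked after their values were seen.

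The region pattern was that 3' UTR sites were mostly lower and coding sites mostly higher in aged cells. Over all regions the share was higher in aged cells at 53.7% of sites under 250 bases from the annotated transcript end. At 8000 bases or more it was higher at 94.2% of sites. A trend in coverage with this distance was argued against as the whole cause. At equal distance the coding sites still exceeded 3' UTR sites by 1.38 (1.10 to 1.997) in log2 ratio of shares, against 1.64 over all distances. This used the 4 distance ranges from 500 to under 8000 bases with at least 20 sites of each region. Sites nearer the end held too few coding sites to compare, so such a trend may still account for a part. A change in the number of cells expressing the gene was also argued against as the whole cause. Within the 73 genes with both kinds of site the median difference was 1.13 (0.857 to 1.57), against 1.64 over all genes. Such a change may still account for a part, and genes with only 1 kind of site do not enter this comparison. A lower edited fraction within methylated aged cells at 3' UTR sites was argued against as the whole cause, since it differed from that at coding sites by -0.0612 (-0.486 to 0.391) in log2, against -2.44 for mean C-to-U. These gaps are not on a like scale, since the table holds no absolute log2 ratio of mean C-to-U under 0.58. The mean is also the share times this fraction, so the result largely restates the gap in shares. Use of other transcript ends, a difference in library chemistry between the ages and an effect of age on m6A stay open, since the table has no reads per site.

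The next pattern, present at 1099 sites, was a higher share of methylated cells with a lower C-to-U fraction within them in aged cells. Deeper reads per cell in the aged libraries, bringing up low-level edits that need no m6A, may contribute: the percentage of sites with C after A differed by -11.9 points (-16.8 to -6.09) between these sites and the others. Whether a few abundant noncoding RNAs took most of the reads stays open: 52.0% (48.6 to 55.7) of the sites outside the 5 genes with the most sites had the pattern, against 62.5% inside, but such RNAs would also act on sites of other genes, so this does not decide. C-to-U within methylated cells lay under 3% at 791 sites in aged and at 206 in young cells. Depth per cell was not measured here, and an effect of age remains untested.

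Splicing and nuclear speckle genes, a group put together after their values were seen, were mostly higher in aged cells. By their largest site 21 of 24 genes (87.5%) were higher, against 54.8% of other genes, and 123 of their 124 sites had a higher share of methylated cells. By mean, 69 of these sites were higher and 55 lower, with 17 of 26 higher in Rbm25, 4 of 4 in Srek1, 4 of 10 in Luc7l3 and 8 of 23 in Srrm2; in the RNA binding and splicing list fixed before, 18 of 30 genes were higher (adjusted p of 0.868). All 24 of those largest sites lay in coding sequence, and random gene sets matched on region reached the same percentage in 10.5% of draws, so that the region of their sites may account for their direction. Whether splicing genes differ from other genes with coding sites in aged cortex stays open as a hypothesis.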
